A study of Mus musculus with 6 samples.

How the data were processed

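The deposited series holds single-cell RNA sequencing of dissociated whole liver from 6 mice, with 1 library per mouse and 3 mice per group. Per the labels, the libraries were 10x Genomics 3′ libraries processed with Cell Ranger 7.1.0 against mm10, and Seurat 4.1.1 was named among the tools. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization, as their whole-number values and unequal library totals show. The labels name liver sinusoidal endothelial cells as the cell type, while the stated protocol is that of whole liver. The counts hold many other cell types, but hepatocyte-like cells were few (266) and no cluster was named as macrophages. The annotation release behind the gene table was not stated, so coordinates were taken from GENCODE release M21 on GRCm38, matched by Ensembl identifier.

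Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored by Scrublet in each library with an expected rate of 0.06. The automatic threshold called 0 and 6 cells in control 2 and control 3, so a common score threshold of 0.2425, taken from the 4 libraries where it worked, was set after the scores were seen. This removed 1109 cells and left 41573. Counts were scaled to 10000 per cell and log transformed, 3000 variable genes and 40 principal components were used for a graph of 20 neighbours, and Leiden clustering at resolution 1 gave 41 clusters (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2). Each cluster was named from marker lists fixed before the data were examined, by a mean marker score of at least 0.5 with a margin of 0.3 over the next list. A cluster in which over 50% of cells were called doublets was left unnamed. A cluster was also left unnamed where under 3 markers were detected, where more of its 10 leading genes were markers of another class than of its own, or where its cells were far shallower than their libraries and no marker was among the 10 leading genes; clusters of usual depth could be named with no marker among them. These naming limits and rules were set after the scores were seen. Named classes are called "-like" since the names rest on transcripts alone, and 2926 cells in 8 clusters stayed unnamed.

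Raw UMIs were summed per library within each class, so that the mouse is the unit of replication. The 10 classes with at least 20 cells in every library were tested for knockout against control with edgeR 4.0.16 (R 4.3.3; TMM normalization, filterByExpr, quasi-likelihood F-test with robust dispersion), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. The same contrasts were run with the Wald test of DESeq2 1.42.0. CPM values are counts scaled to the TMM-normalised library size, and values after ± are standard deviations over 3 mice. The 13 classes with at least 10 cells on average per library were tested for their share of cells with edgeR on cell numbers, beside an exact two-sided permutation test. The smallest p that permuting 3 against 3 mice can give is 0.1. Of 37 gene lists fixed before the data were examined, those with at least 5 tested members were tested in each class with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with the estimated correlation and fry run beside it. The comparisons, their tests, the gene lists and most alternatives were also chosen before the data were examined.

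The genes named were set by rule: the targeted gene; in endothelial-like cells up to 10 higher and 10 lower genes past the threshold, and in other classes up to 4 each way, with a mean log2 CPM of at least 4 and no overlap between groups; where fewer than 3 passed in a direction, those of smallest unadjusted p up to 3; up to 4 members of smallest p of each list past its test; and up to 2 members in endothelial-like cells for STING pathway components, interferon-stimulated genes, chemokines, leukocyte adhesion molecules, sinusoidal identity, capillarization and angiocrine factors. Any other gene is said to have been chosen after its values were seen.

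A planned test of whether the genotype effect differs between endothelial-like and monocyte or macrophage-like cells was not run, since no cluster took that name, and T-like cells took its place as an addition. A further test on T-like cells, run after Il23r had been called, is not reported here, and the count of T-like cells with an Il23r UMI was added then as well. Pairs of libraries shared between 0.1% and 0.31% of barcodes, and no library duplicated another among the 15 pairs.

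The tests were tried on simulated data made from these libraries. With 100 genes each moved by a log2 fold change of 1 or 2, edgeR recovered 46% and 90% of them in endothelial-like cells. It made 15 false calls beside these, among 11994 genes. It recovered 73% and 91% in T-like cells (16 false calls), 51% and 90% in cDC1-like cells (7), and 68% and 95% in mesothelial-like cells (19). False calls are to be read against the genes recovered rather than all genes tested. Counts were drawn independently for each gene, without the shared differences between libraries of the real data. The share test recovered 90% of 20 simulated changes of 3 on the log2 scale, with 2 false calls, at a set dispersion of 0.3. The largest class change in the real data was -1.20, so power for changes of that size was not measured. A simulated list moved by 0.5 was recovered in each of these classes, with 2 false list calls in endothelial-like and 1 in mesothelial-like cells. Alternatives covered normalization, the count filter, depth, doublets, cell filters, clustering resolution, the replicate number as a block, the test and each library left out.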

Results

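Livers of 6 mice were profiled after 12 weeks of western diet with carbon tetrachloride, a regimen that produces metabolic dysfunction-associated steatohepatitis (MASH), in which a fatty liver becomes inflamed and scarred. The mice had eaten chow until 8 weeks of age. In 3 of them, floxed Sting alleles were targeted for deletion in endothelium by a Cre recombinase under the Cdh5 promoter. The controls were 3 littermates with floxed alleles and no Cre. Whether the alleles were also deleted in immune cells was not tested. STING is the adaptor through which cytosolic DNA switches on interferon and NF-kB genes, and the series asks how its loss from endothelium alters liver immune cells. The 3 control libraries held 63636671, 65000706 and 55017937 UMIs, and the 3 knockout libraries held 72058613, 55448411 and 73867890. Between 5133 and 9212 barcodes were recorded per library, 44656 in all, with median depths of 4695 to 7345 UMIs.

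T-like cells were the most frequent class, with 15300 of 41573 cells, followed by B-like cells with 8299. Endothelial-like cells (2599), NK/ILC1-like cells (2572), mesothelial-like cells (2537) and cholangiocyte-like cells (2257) came next, then stellate/fibroblast-like cells (1227), neutrophil-like cells (1191), type 1 conventional dendritic (cDC1-like) cells (1124) and plasma-like cells (792). Mature dendritic, hepatocyte and plasmacytoid dendritic classes held 301, 266 and 182 cells. At clustering resolution 1 no cluster took the name of Kupffer cells, monocytes or macrophages, type 2 conventional dendritic cells (cDC2), basophils or mast cells, platelets or erythroid cells, so liver macrophages could not be compared; at resolution 2 a cluster of 360 cells took the cDC2 name. Cells without a name made up 7.04% ± 1.92 of control and 6.82% ± 1.78 of knockout libraries.

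The question of whether the knockout altered the make-up of the recovered cells was addressed by the share of each class. Shares also depend on dissociation, so they need not give the make-up of the liver. Stellate/fibroblast-like cells, a class that pools a cluster led by smooth muscle genes such as Myh11 and Acta2 (696 cells) with one led by matrix genes such as Lum and Col1a1 (509 cells), made up 4.06% ± 1.73 of cells in controls and 1.76% ± 0.902 in knockouts. Mature dendritic-like cells made up 1.09% ± 0.626 and 0.471% ± 0.232. B-like cells stood at 16.6% ± 3.45 and 23.8% ± 4.29, T-like cells at 36.2% ± 13.8 and 35.6% ± 6.08, and endothelial-like cells at 7.08% ± 4.31 and 5.92% ± 2.04. None of these passed the test: edgeR called 0 of 13 classes, 0 had an unadjusted p under 0.05, and the exact permutation test called 0. The smallest adjusted p was 0.428, for the stellate/fibroblast-like class (log2 fold change -1.20, SE 0.588) and the mature dendritic-like class (-1.20, SE 0.603), and the groups overlapped in both. Within endothelial-like cells, large-vessel cells made up 28.1% ± 11.4 in controls and 37.0% ± 11.3 in knockouts, lymphatic cells 17.8% ± 9.87 and 8.84% ± 3.23, and sinusoidal cells 6.98% ± 8.79 and 10.2% ± 7.87. Exact two-sided permutation p values for the 4 endothelial subtypes, an unnamed one included, ran from 0.4 to 0.7, where 0.1 is the smallest possible.

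**Figure D1:**
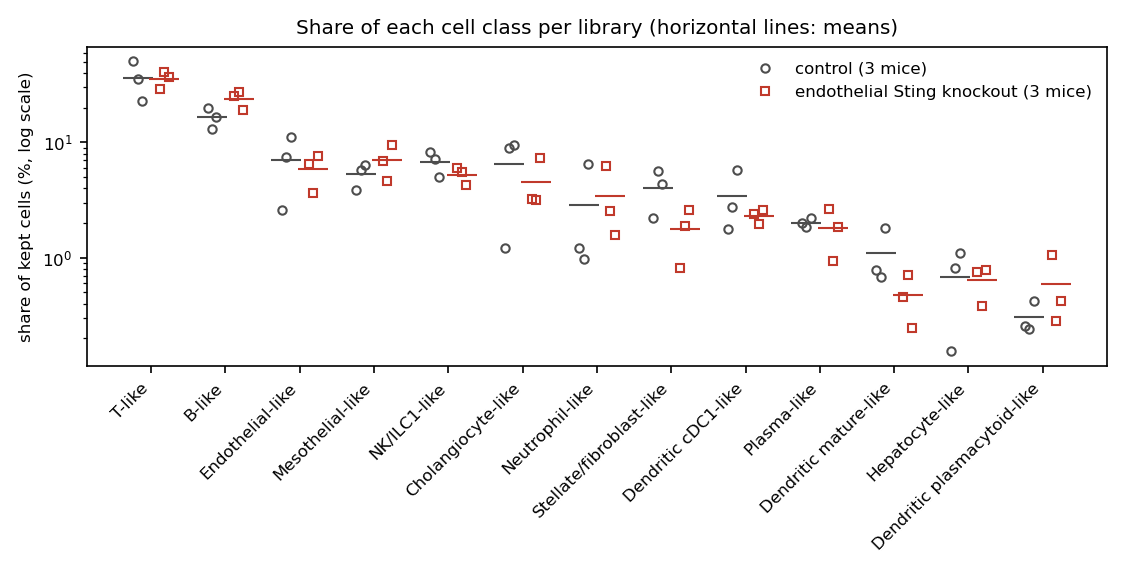
Share of each cell class among the kept cells of a library, in percent on a log axis, for 3 control and 3 knockout mice; points are mice and lines are group means. Stellate/fibroblast-like cells averaged 4.06% in controls and 1.76% in knockouts, with overlapping mice.

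Sting1, the targeted gene, was lower in knockout endothelial-like cells, at 19.5 ± 4.24 CPM against 27.2 ± 0.769 in controls, a log2 fold change of -0.46 (SE 0.178). All 3 knockout values (21.7, 14.6 and 22.1) lay under all 3 control values (28.0, 26.4 and 27.3). The groups did not overlap in 12.7% of the genes tested in this class, where chance gives 10%. This did not pass the test over all genes (unadjusted p = 0.0299, adjusted p = 0.751). The gene (ENSMUSG00000024349) lies on the minus strand of chromosome 18 from 35733679 to 35740554 (mm10). A 3′ tag can lie outside the floxed exons, which the labels do not give, so Sting1 counts need not follow the deletion. Sting1 in other classes was looked at after these values were seen. It was lower in B-like cells (8.10 ± 1.44 against 4.67 ± 0.629 CPM, log2 fold change -0.79, SE 0.23, adjusted p = 0.546) and NK/ILC1-like cells (17.2 ± 2.49 against 10.2 ± 0.928 CPM, -0.72, SE 0.226, adjusted p = 0.635), without passing the test; the groups did not overlap, as in 10.9% of genes in B-like and 11.5% in NK/ILC1-like cells, where chance gives 10%. In T-like cells the difference was 0.01 (SE 0.137), at 13.2 ± 1.5 and 13.2 ± 0.977 CPM. Cholangiocyte-like, cDC1-like, mesothelial-like and plasma-like cells had overlapping groups, with log2 fold changes of 0.16, 0.40, 0.24 and 0.16.

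**Figure D2:**
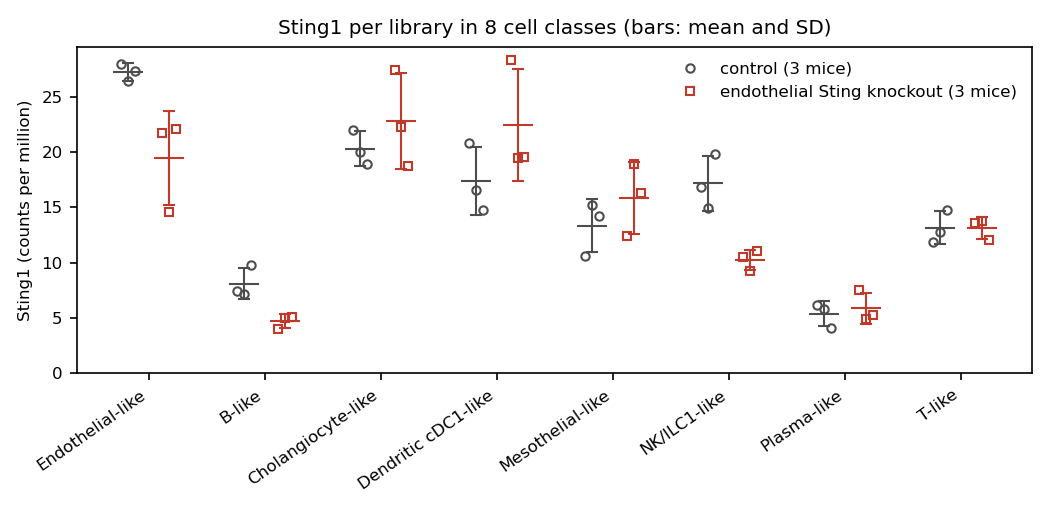
Sting1 level in CPM in each class where it was tested, for 3 control and 3 knockout mice; points are mice and bars are means with SD. In endothelial-like cells the knockout mice lie between 14.6 and 22.1 and the controls between 26.4 and 28.0.

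The genes of smallest p in endothelial-like cells, 3 higher and 3 lower in knockout mice, did not pass the test. Kctd12b was at 41.2 ± 1.04 CPM against 21.4 ± 1.57 in controls (log2 fold change 0.94, SE 0.126, adjusted p = 0.672). The C-type lectin genes Clec1a and Clec14a, both markers of endothelium, differed by 0.55 (SE 0.109) and 0.79 (SE 0.162). Sema4d, a semaphorin, was at 21.9 ± 0.878 against 45.9 ± 9.03 CPM (-1.07, SE 0.166, adjusted p = 0.751), Dusp2, a phosphatase induced on activation, differed by -0.83 (SE 0.141), and the actin-binding gene Tmsb10 by -0.90 (SE 0.161). edgeR called 0 of 12192 genes, with 802 at an unadjusted p under 0.05 (318 higher, 484 lower) against 609.6 expected, and DESeq2 called 13 (2 higher, 11 lower). Without control replicate 3, edgeR called 81.

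Tested as lists, the same cells showed lower stress and inflammatory genes and higher endothelial identity genes. The immediate early and heat shock genes that tissue dissociation induces were lower in 23 of 24 members, with a median log2 fold change of -0.36, and the list passed (camera, adjusted p = 6.8e-14; adjusted p = 0.319 with an estimated correlation). Hspa1b, a heat shock chaperone, was at 3185 ± 451 against 6503 ± 1710 CPM (-1.03, SE 0.217), the chaperonin gene Hspe1 differed by -0.62 and the stress factor Atf3 by -0.62; adjusted over the list alone, 6 members passed, and 0 over all genes. NF-kB and inflammatory cytokine genes were lower in 27 of 29 members (median -0.38, adjusted p = 2.18e-08; adjusted p = 0.297 with an estimated correlation), among them the cytokine Lif (-2.72, SE 0.517) and the transcription factor Cebpb (-1.10, SE 0.247). Adjusted over the list alone, 2 of them passed, and 0 over all genes. The level of Lif was low, at 1.51 ± 0.702 against 9.81 ± 4.94 CPM in controls. Chemokines were lower in 14 of 16 members (median -0.49, adjusted p = 0.000247; adjusted p = 0.297 with an estimated correlation), with Ccl7 at -1.47 (SE 0.481) and Ccl5 at -0.94 (SE 0.323). Ccl7 was low as well, at 1.55 ± 0.898 against 4.60 ± 1.67 CPM in controls. All 3 knockout mice lay under all 3 controls in the mean of the chemokine list and of the dissociation list, while they overlapped for the NF-kB list. Ccl5 is also a transcript of T and NK cells, and whether its difference here lies in endothelial cells was not tested.

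Antigen presentation lists were lower as well. MHC class I genes were lower in 20 of 21 members (median -0.13, adjusted p = 0.00383; adjusted p = 0.297 with an estimated correlation), with H2-Q6 at -0.31 (SE 0.116), and MHC class II genes in 14 of 14 (median -0.46, adjusted p = 0.00931; adjusted p = 0.549 with an estimated correlation), with the costimulatory gene Cd80 at -1.53 (SE 0.473). Interferon-gamma-induced genes, such as the GTPase genes Gbp9 (-0.46) and Tgtp1 (-0.91), were lower in 19 of 25 (median -0.18, adjusted p = 0.034; adjusted p = 0.588 with an estimated correlation). Adjusted over the list alone, 0 members of these lists or of the chemokines passed, and 0 over all genes. Levels were low for Cd80 (1.96 ± 1.0 against 5.14 ± 2.03 CPM in controls) and Tgtp1 (3.185 ± 0.717 against 5.974 ± 1.65). With each library left out in turn, the MHC class II call was lost in 2 of 6 runs and the interferon-gamma call in 3 of 6, both with a changed sign without control replicate 3 (adjusted p = 0.825 and 0.517, the highest of the 6 runs). Interferon-stimulated genes did not pass (24 of 43 higher, median 0.04, mean -0.03, adjusted p = 0.983), with Ifi27l2a at -1.35 (SE 0.348) and Slfn8 at -0.84 (SE 0.249), and neither did STING pathway components (8 of 16 lower, adjusted p = 0.338) with Ikbke at -0.83 (SE 0.394); adjusted over the list alone or over all genes, 0 members of either passed.

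Sinusoidal identity genes, a list chosen to mark the fenestrated endothelium of the liver, were higher in 20 of 23 members (median 0.36, camera adjusted p = 0.00227, and 0.549 with an estimated correlation). Ntn4 stood at 0.52 (SE 0.231), but it was also among the 10 leading genes of cluster 14, named large-vessel. Sgk1 stood at -0.42 (SE 0.169). The mix of subtypes in this class varied between mice, with sinusoidal cells at 1.378% to 17.105% of endothelial-like cells in controls and 3.81% to 18.985% in knockouts. The list passed in cluster 9 alone, of no named subtype (adjusted p = 0.00296), and cluster 14 alone, of large-vessel cells (2.45e-05), and was not tested in the sinusoidal cluster alone. The call therefore need not reflect sinusoidal identity. It was lost with the library split as a term (0.127) and without control replicate 2 (0.173) or knockout replicate 1 (0.555), in a range of 3.29e-06 to 0.603 over its alternatives. Capillarization and large-vessel genes were higher in 18 of 27 (median 0.16, adjusted p = 0.0127; adjusted p = 0.297 with an estimated correlation), with Ly6c1 at 0.69 (SE 0.239) and the basement membrane gene Hspg2 at 0.36 (SE 0.124). Leukocyte adhesion molecules were higher in 12 of 15 (median 0.18, adjusted p = 0.0411; adjusted p = 0.319 with an estimated correlation), with Esam at 0.25 (SE 0.151) and Alcam at -0.41 (SE 0.237). Angiocrine factors did not pass (14 of 25 higher, adjusted p = 0.808), with Dll1, a Notch ligand, at -0.63 (SE 0.158) and Pdgfb at 0.63 (SE 0.176). Adjusted over the list alone, 0 members of these 4 lists passed, and 0 over all genes. Transcripts of other cell types moved along with these groups: T cell transcripts were lower in 8 of 10 members (median -0.59, adjusted p = 0.00018; adjusted p = 0.297 with an estimated correlation), with Trbc2 at -1.02 (SE 0.27), and general endothelial transcripts were higher in 14 of 14 (median 0.34, adjusted p = 0.00206; adjusted p = 0.416 with an estimated correlation), with Ptprb at 0.37 (SE 0.166). Adjusted over the list alone, 1 T cell transcript passed and 0 endothelial transcripts did, and 0 over all genes. Cytotoxicity genes of T and NK cells were lower in 11 of 15 (median -0.78, adjusted p = 3.64e-05; adjusted p = 0.297 with an estimated correlation), with Nkg7 at -0.78 (SE 0.237). Nuclear genes of oxidative phosphorylation were lower in 22 of 34 (adjusted p = 0.000258) and ribosomal protein genes in 26 of 36 (adjusted p = 0.000157), with Atp5e at -0.66 (SE 0.169) and Rpl35 at -0.57 (SE 0.131); both lists had an adjusted p = 0.53 with an estimated correlation. In these 3 lists 0 members passed adjusted over the list alone or over all genes. Of 34 lists tested in endothelial-like cells, camera with the preset correlation called 17 (4 higher, 13 lower; 11 without knockout replicate 2, of which 2 higher), and 16 with the library split as a term (1 higher, 15 lower), and camera with the estimated correlation and fry each called 0.

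**Figure D3:**
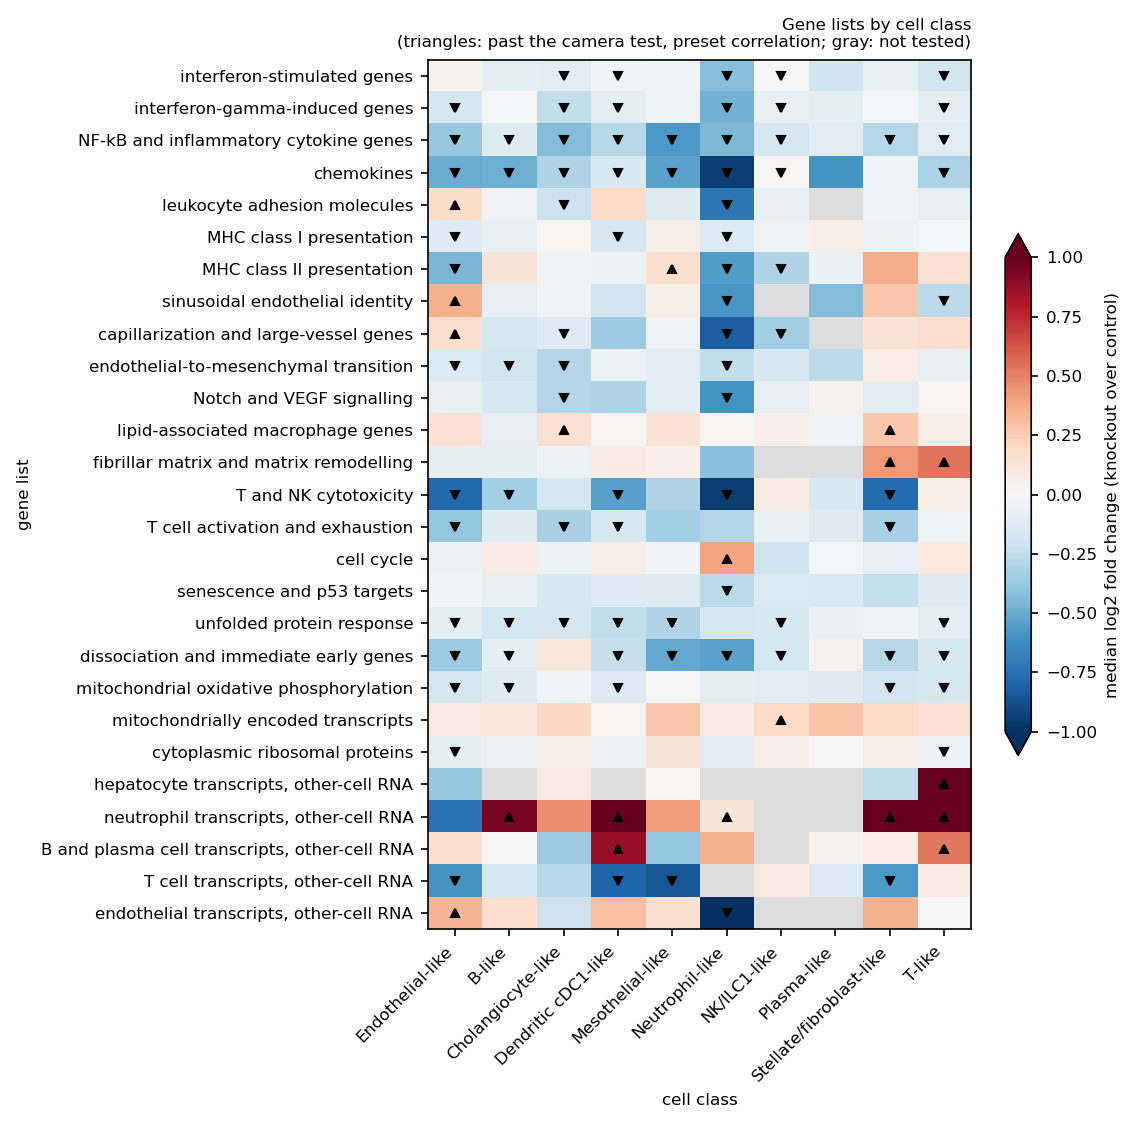
Median log2 fold change (knockout over control) of the members of fixed gene lists, by list and cell class; colour gives the median, triangles mark lists past the camera test at its preset correlation, and gray marks lists not tested. NF-kB and inflammatory cytokine genes were lower past that test in 9 of 10 classes, and no list passed with an estimated correlation.

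Il23r, a subunit of the interleukin 23 receptor, fell in T-like cells of knockout mice. It was at 86.4 ± 6.83 CPM against 171 ± 11.2 in controls, with a log2 fold change of -0.99 (SE 0.0969, adjusted p = 0.0259), and all 3 knockout values (79.7, 93.4 and 86.2) lay under all 3 control values, of which the highest was 184. The gene (ENSMUSG00000049093, chromosome 6 from 67422932 to 67491855, minus strand) was the single gene called among 12925 in this class. Counted after this call, cells with an Il23r UMI made up 12.36% ± 1.33 of T-like cells in controls and 7.37% ± 0.57 in knockouts (exact two-sided permutation p = 0.1, the smallest possible), and these cells held 7.97 ± 0.6 and 7.18 ± 0.86 Il23r UMIs each (exact p = 0.2). Fewer cells with the transcript thus go along with the lower class level, and the class value does not separate a change in the mix of T cells from a change within them. Other genes of small p were the circadian repressor Nr1d1 (-0.74, SE 0.119, adjusted p = 0.538) and Pxdc1 (-0.84, SE 0.156), and on the higher side Inpp4b (0.49, SE 0.094), Mpp7 (0.55, SE 0.105) and Hdac9 (1.32, SE 0.287), none of which passed. The Il23r call was lost with any 1 library left out (log2 fold change -1.05 to -0.93, adjusted p = 0.0719 to 0.166). DESeq2 called 24 genes in T-like cells.

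Ccl5, a chemokine that draws T cells and monocytes, fell in cDC1-like cells, which present antigen to CD8 T cells. It was at 64.9 ± 10.1 CPM against 172 ± 25.5 (log2 fold change -1.41, SE 0.173, adjusted p = 0.0138), with all 3 knockout values (53.7, 73.2 and 67.9) under all 3 control values (160, 201 and 154). The gene (ENSMUSG00000035042) lies on the minus strand of chromosome 11 from 83525778 to 83530518. The interferon-induced gene Oasl1 was at 37.2 ± 3.13 against 80.3 ± 7.37 CPM (-1.12, SE 0.166) and narrowly missed the threshold (adjusted p = 0.0558), as further off did the receptor gene Cxcr4 (-0.81, SE 0.167). On the higher side Ebf1, a B cell gene, differed by 1.63 (SE 0.263), and Creb5 was at 42.0 ± 5.67 against 20.5 ± 3.62 CPM, without passing. T cell transcripts were lower in 9 of 9 members in these cells (median -0.79, adjusted p = 5.75e-07; adjusted p = 0.163 with an estimated correlation), and B and plasma cell transcripts were higher in 7 of 8 (median 0.87, adjusted p = 9.24e-09; adjusted p = 0.186 with an estimated correlation). Adjusted over the list alone, 0 T cell transcripts and 4 B and plasma cell transcripts passed, and 0 over all genes. Cells that held a T or NK cell UMI made up 29.2% of cDC1-like cells (328 of 1124) and carried 71.0% of their Ccl5 UMIs (1301 of 1832), and without them the log2 fold change was -1.56 (SE 0.352, adjusted p = 0.769). The call was also lost without control replicate 1, control replicate 2 or knockout replicate 1 (adjusted p = 0.124, 0.075 and 0.111).

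**Figure D4:**
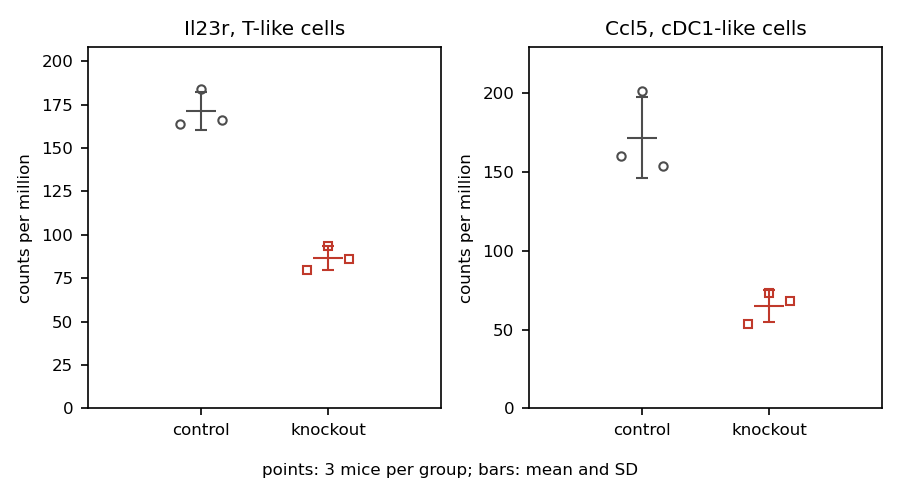
Il23r in T-like cells (left) and Ccl5 in cDC1-like cells (right), in CPM, for 3 control and 3 knockout mice; points are mice and bars are means with SD. The knockout mice lie between 79.7 and 93.4 for Il23r and between 53.7 and 73.2 for Ccl5, under all controls.

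In the other 7 classes named genes differed without passing the test. B-like cells had lower S100a6, a calcium-binding gene, at 71.6 ± 14.5 against 154 ± 18.1 CPM (-1.11, SE 0.146, adjusted p = 0.061), and lower Anxa2 (-0.86, SE 0.141) and Mt1, a metallothionein gene (-1.47, SE 0.243). NK/ILC1-like cells had lower Cfap53 (-1.36, SE 0.22, adjusted p = 0.0756) and lower mitochondrial chaperonin genes Hspe1 (-0.66, SE 0.124) and Hspd1 (-0.64, SE 0.121). Mesothelial-like cells had higher Csrp2 (238 ± 14.4 against 138 ± 17.8 CPM, 0.78, SE 0.114), Pcdh15 (1.16, SE 0.168) and Tst (0.57, SE 0.0875), and lower Ythdc2 (-0.71, SE 0.107), the kinase gene Map2k1 (-0.58, SE 0.0909) and Nfatc1 (-1.34, SE 0.204), all with an adjusted p of 0.0935. Cholangiocyte-like cells had lower Lif (-0.83, SE 0.147) and the chemokine Cxcl10 (-0.70, SE 0.131) and higher Gsta3, a glutathione transferase gene (0.75, SE 0.131). In neutrophil-like cells Ccl5 was at 35.3 ± 8.68 against 219 ± 60.7 CPM (-2.64, SE 0.34, adjusted p = 0.168). Plasma-like cells had lower Tbx21, the gene of the transcription factor T-bet (-1.34, SE 0.301), and stellate/fibroblast-like cells lower Cd247, a T cell receptor chain gene (-1.11, SE 0.269). Ccl5, Tbx21 and Cd247 are also transcripts of T and NK cells. RNA of those cells in the barcodes of these classes was not tested as a source.

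Counts of genes in these classes were as follows. In B-like cells edgeR called 0 of 11262 genes, with 663 at an unadjusted p under 0.05 against 563.1 expected, and DESeq2 called 11. For cholangiocyte-like cells edgeR called 0 of 13278 (1229 at an unadjusted p under 0.05, 663.9 expected) and DESeq2 25. Among 13105 genes in mesothelial-like cells edgeR called 0, with 2247 at an unadjusted p under 0.05 against 655.2 expected, and DESeq2 called 280; without control replicate 1 edgeR called 103. Neutrophil-like cells gave 0 of 7941 with edgeR (134 at an unadjusted p under 0.05, 397 expected) and 4 with DESeq2. NK/ILC1-like cells gave 0 of 9661 with edgeR (624 at an unadjusted p under 0.05, 483 expected) and 9 with DESeq2. Plasma-like cells gave 0 of 8970 with edgeR (490 at an unadjusted p under 0.05, 448.5 expected) and 1 with DESeq2. Stellate/fibroblast-like cells gave 0 of 11104 with edgeR (189 at an unadjusted p under 0.05, 555.2 expected) and 0 with DESeq2. In cDC1-like cells, where edgeR called Ccl5 among 10050 genes, DESeq2 called 12.

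Across classes most lists past the test were lower in knockout mice. NF-kB and inflammatory cytokine genes were lower past the camera test in 9 of 10 classes (adjusted p = 0.297 or more with an estimated correlation), chemokines in 8 (0.275 or more), the immediate early and heat shock genes in 8 (0.319 or more) and genes of the unfolded protein response in 7 (0.451 or more). Transcripts of other cell types moved as well: T cell transcripts were lower in 4 of 9 classes (adjusted p = 0.163 or more with an estimated correlation), cytotoxicity genes of T and NK cells in 5 of 10 (0.19 or more), and neutrophil transcripts were higher in 5 of 8, the neutrophil-like class among them (0.45 or more). Interferon-gamma-induced genes were lower in 6 classes and interferon-stimulated genes in 5 (adjusted p = 0.45 or more with an estimated correlation in both). Some of these calls depended on single libraries. Leaving out each library, the interferon-stimulated call in cholangiocyte-like cells was lost or reversed in 4 of 6 runs (highest camera adjusted p = 0.884). The interferon-gamma call in endothelial-like cells was lost or reversed in 3 of 6. In T-like cells interferon-stimulated genes were lower in 32 of 44 members (median -0.18, adjusted p = 1.05e-05; adjusted p = 0.597 with an estimated correlation), with Oasl1 at -1.01 (SE 0.249) and 0 members past the test adjusted over the list alone or over all genes. In NK/ILC1-like cells the interferon-stimulated and chemokine lists passed as lower with medians of 0.0049 and 0.0099 and means of -0.22 and -0.48. The interferon-stimulated member of smallest p in these cells, Ifi27l2a, was higher (1.00, SE 0.273). With each library left out in turn, that list call was lost or reversed in 3 of 6 runs (highest camera adjusted p = 0.986, without knockout replicate 2). There Cxcl10, which recruits T cells, was at 40.8 ± 12.6 against 158 ± 63.7 CPM (-1.91, SE 0.344). Of 317 tests of a list in a class, camera with the preset correlation called 103 (19 higher, 84 lower), while camera with the estimated correlation called 0 (lowest adjusted p = 0.163) and fry called 0 (lowest adjusted p = 0.0969). The number of calls at the preset correlation does not set the genotype apart. In every class but the endothelial-like one, some split of the libraries that mixed the genotypes called as many lists or more.

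Whether the genotype effect differed between endothelial-like and T-like cells was tested gene by gene. Sema4d had the smallest p, with an endothelial effect lower than the T cell effect by a log2 difference of -0.96 (SE 0.147), followed by Pdgfb with 1.18 (SE 0.191); both had an adjusted p of 0.425. edgeR called 0 of 13838 genes, with 708 at an unadjusted p under 0.05 against 691.9 expected, and DESeq2 was not run for this test. Without control replicate 3 it called 26. Looked at after these values were seen, the leading genes included T cell genes such as Bcl11b, Trbc2 and Cd5, beside others such as Prox1 and Krt8. These T cell genes were lower in knockout endothelial-like cells and little changed in T-like cells. RNA of T cells in endothelial-like barcodes was not tested as a source of such differences, that of Sema4d included.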

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

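Most alternatives were fixed before the data were examined. Chosen after the results were seen were the automatic Scrublet thresholds, the single endothelial clusters, neutrophil-like cells without cluster 33, stellate/fibroblast-like cells without cluster 17, T-like cells without cluster 13, the 2 tests on cDC1-like cells without cells holding UMIs of another type, the library split as a term, and the alternatives of the comparison with T-like cells. The planned comparison with monocyte or macrophage-like cells and its alternatives were not run. Of the values for single named genes under an alternative, 2796 stayed on their side of the threshold with the same direction. A further 10 no longer passed, 7 changed sign and the remainder passed it with the same direction. Only Il23r in T-like cells and Ccl5 in cDC1-like cells passed in the main fit, so only they could be lost. All 10 losses fell on them, over 18 and 19 alternatives, and most of the 2796 had not passed in the main fit. Of the values for single lists, 1154 kept call and direction, 433 were lost and 12 changed sign. Where a count or sign moved, the cause was not tested. Cells per library were as few as 57 in the stellate/fibroblast-like, 59 in the plasma-like and 86 in the neutrophil-like class.

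Sting1 in endothelial-like cells ran from -0.75 (cluster 14 only) to -0.22 (cluster 9 only), with an adjusted p from 0.4 to 1 over 19 alternatives. With DESeq2 the number of genes called was 13 in endothelial-like, 11 in B-like, 25 in cholangiocyte-like, 12 in cDC1-like, 280 in mesothelial-like, 4 in neutrophil-like, 9 in NK/ILC1-like, 1 in plasma-like and 24 in T-like cells. With no filter on low counts edgeR called 86 genes in B-like, 17 in cholangiocyte-like, 72 in cDC1-like, 225 in mesothelial-like, 3 in neutrophil-like, 50 in NK/ILC1-like, 67 in plasma-like and 17 in T-like cells, 178 genes in the comparison of endothelial-like with T-like cells, and 12 lists in mesothelial-like and 4 in plasma-like cells. Thinned to the lowest library total, B-like, cholangiocyte-like and neutrophil-like cells gave 1 gene each, and Sting1 in T-like cells was -0.15. Under automatic Scrublet thresholds cholangiocyte-like cells gave 1 gene and Lgals3 in stellate/fibroblast-like cells was -0.022. cDC1-like cells gave 2 genes under DESeq2 size factors, with at most 10% mitochondrial UMIs, at clustering resolution 2, and without cells holding a mature dendritic cell UMI, and 0 without cells holding a T or NK cell UMI. With doublets kept, 11 lists passed in neutrophil-like and 2 in plasma-like cells. In endothelial cluster 9 only, 10 lists passed, and in cluster 14 only, 11. Neutrophil-like cells gave 4 genes and 14 lists without cluster 33, where the list of endothelial-to-mesenchymal transition changed sign (adjusted p = 0.958, in a range of 6.25e-05 to 0.958 over its alternatives). Stellate/fibroblast-like cells gave 0 genes and 4 lists (0 higher, 4 lower) without cluster 17. With the estimated correlation camera called 0 lists in each class, and fry called 0 lists in each class. The share of hepatocyte-like cells changed sign under TMM over classes (log2 fold change 0.092).

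The labels do not say whether replicate numbers pair the mice. For replicates 1, 2 and 3, deviations of libraries with the same number correlated across genes at -0.0234, 0.241 and 0.0813 in endothelial-like, -0.104, 0.256 and -0.0202 in T-like, and 0.00501, 0.242 and 0.181 in B-like cells, where genes are not independent replicates. Replicate 2 correlated most with its own number in each of these classes and replicate 3 in B-like cells alone, so a pairing was neither shown nor excluded. With the replicate number as a block edgeR called 1 gene in endothelial-like, 28 in B-like, 5 in cDC1-like, 7 in mesothelial-like, 2 in neutrophil-like, 14 in NK/ILC1-like and 2 in plasma-like cells, and camera 11 lists in mesothelial-like and 3 in plasma-like cells; with this block the shares of hepatocyte-like and T-like cells were 0.14 and 0.039. With the library split as a term, edgeR called 5 genes in B-like, 9 in NK/ILC1-like, 2 in cDC1-like and 2 in T-like cells, camera 16 lists in endothelial-like (1 higher, 15 lower), 14 in B-like, 12 in mesothelial-like, 14 in NK/ILC1-like and 6 in plasma-like cells, Sting1 in T-like cells was -0.0065, and the share of T-like cells was 0.23.

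Leaving out each library in turn, the number of genes called ran from 0 to 81 in endothelial-like (81 without control 3), 0 to 1 in B-like, 0 to 6 in cholangiocyte-like, 0 to 6 in cDC1-like, 0 to 103 in mesothelial-like (103 without control 1), 0 to 2 in neutrophil-like, 0 to 3 in NK/ILC1-like and 0 to 1 in plasma-like cells, was 0 in T-like cells throughout, and ran from 0 to 26 for the comparison with T-like cells (26 without control 3). The number of lists ran from 11 to 18 in endothelial-like (1 to 5 of them higher), 7 to 20 in cholangiocyte-like, 5 to 11 in mesothelial-like, 9 to 22 in neutrophil-like, 2 to 13 in NK/ILC1-like, 0 to 8 in plasma-like, 5 to 13 in stellate/fibroblast-like and 6 to 15 in T-like cells. Ccl5 in cDC1-like cells ran from -1.51 to -1.27 (adjusted p = 0.0205 to 0.124), Sting1 from -0.094 to 0.28 in plasma-like and -0.064 to 0.093 in T-like cells. Log2 fold changes of shares ran from -0.87 to 0.045 for cDC1-like, -0.65 to 0.24 for endothelial-like, -0.56 to 0.41 for hepatocyte-like, -0.48 to 1.66 for neutrophil-like, -0.54 to 0.15 for plasma-like and -0.27 to 0.29 for T-like cells. Lists that changed sign had adjusted p values of 0.00019 to 0.517 (interferon-gamma-induced) and 6.17e-08 to 0.825 (MHC class II) in endothelial-like cells, 1.29e-06 to 0.884 (interferon-stimulated) in cholangiocyte-like cells, 0.000161 to 0.849 (chemokines) in cDC1-like cells, 1.78e-09 to 0.971 (NF-kB), 3.28e-05 to 0.991 (MHC class II), 0.00128 to 0.991 (Notch and VEGF) and 3.92e-10 to 0.991 (cell cycle) in neutrophil-like cells, 0.000213 to 0.986 (interferon-stimulated) in NK/ILC1-like cells, and 1.13e-07 to 0.505 (ribosomal proteins) and 4.66e-08 to 0.979 (neutrophil transcripts) in T-like cells.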

Other observations

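The tests of explanations, the counts over other splits and the fit with a library split were chosen after the results they measure were seen. Several further gene groups differed between knockout and control mice. Stellate/fibroblast-like cells had higher fibrillar matrix genes, in 25 of 28 members (median log2 fold change 0.43, adjusted p = 4.39e-06; adjusted p = 0.845 with an estimated correlation), with elastin, Eln, at 0.55 (SE 0.262); 0 members passed adjusted over the list alone or over all genes. Cluster 17, led by smooth muscle genes, held 120, 385 and 32 cells of this class in controls and 12, 75 and 72 in knockouts. Without it the matrix list did not pass (adjusted p = 0.288, in a range of 1.34e-12 to 0.965 over its alternatives). With that cluster kept, the call was also lost without knockout replicate 1 (camera, adjusted p = 0.103). Mesothelial-like cells had higher MHC class II genes, in 10 of 12 members (median 0.17, adjusted p = 0.00578; adjusted p = 0.727 with an estimated correlation), of which 5 passed adjusted over the list alone and 0 over all genes, with H2-DMb1 at 0.51 (SE 0.108). Neutrophil-like cells had higher cell cycle genes, in 22 of 27 (median 0.40, adjusted p = 6.19e-06; adjusted p = 0.527 with an estimated correlation), a call lost without control replicate 3 (adjusted p = 0.991) or knockout replicate 1 (0.219), in a range of 3.92e-10 to 0.991 over its alternatives; 0 members passed adjusted over the list alone or over all genes. Cluster 33, of cycling neutrophil-like cells, held 257 cells, 158 of them from knockout 1. Without it fewer than 5 members passed the count filter, so the list could not be tested. Most of the 27 members thus met the filter only with the cells of this cluster. T-like cells had higher hepatocyte transcripts, in 9 of 9 (median 1.15, adjusted p = 2.83e-11; adjusted p = 0.448 with an estimated correlation), with Apoa1, an abundant hepatocyte gene, at 1.74 ± 0.649 against 0.275 ± 0.0498 CPM; 5 members passed adjusted over the list alone and 0 over all genes. Cluster 13, of CD8 T-like cells, held 925 cells, 684 of them from control 1.

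Ccl5 was lower in cDC1-like cells of all 3 knockout mice. Cells of the class that held a mature dendritic cell UMI do not account for it. Without them the log2 fold change was -1.489 (SE 0.223, edgeR adjusted p = 0.0458). Mature dendritic cells, or their RNA, in barcodes without such a UMI would remain in this test, so they are not excluded as a source. For RNA of T and NK cells, rich in Ccl5, as the source the values point both ways. In the other classes where it was named, neutrophil-like (-2.64, SE 0.34) and endothelial-like (-0.94, SE 0.323), Ccl5 was lower too, without passing over all genes. That naming went by smallest p, and further classes were not compared. Cells with a T or NK cell UMI carried 71.02% of the Ccl5 UMIs, and T cell transcripts were lower in 9 of 9 members in this class. Against it, such cells numbered 54 of 138, 60 of 240 and 79 of 275 cDC1-like cells in controls and 51 of 169, 38 of 124 and 46 of 178 in knockouts, their share of the Ccl5 UMIs was 57.0%, 79.46% and 72.24% against 79.45%, 63.36% and 67.22%, and Ccl5 in T-like and NK/ILC1-like cells overlapped between groups. Without those cells the value was -1.56 with a wider spread (SE 0.352, adjusted p = 0.769), so this source and a change within cDC1-like cells cannot be told apart, and the knockout stays open as the cause.

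The immediate early, heat shock and NF-kB lists were lower in most classes, in 17 of 20 pairs of class and list past the camera test at its preset correlation, and in 0 with an estimated correlation (lowest adjusted p = 0.297 for NF-kB and 0.319 for immediate early and heat shock genes). After thinning class sums to the lowest library total 16 pairs still passed at the preset correlation, which argues against the depth of the sums; depth per cell was not matched. Handling of single mice or libraries, such as time in dissociation, may contribute: deviations of libraries from their group mean correlated between classes at 0.339 on average, in a range from -0.823 to 0.912. With 3 mice per group handling and genotype cannot be told apart, and the knockout stays open as the cause.

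The 6 libraries split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For genes in endothelial-like cells the real count was 0 and the highest other 18, and 10 of the 10 splits gave as many; for lists the real count was 17 and the highest other 16, and 1 split, the real one, gave as many. For genes, with the real count of 0 and so 10 splits as large each, the highest other was 53 in B-like, 0 in cholangiocyte-like, 13 in mesothelial-like, 207 in neutrophil-like, 4 in NK/ILC1-like, 184 in plasma-like and 759 in stellate/fibroblast-like cells, 1 for class shares and 0 for the comparison of endothelial-like with T-like cells. In cDC1-like cells 4 splits gave at least the 1 gene of the real groups, the highest other being 3, and in T-like cells 2 splits did, the highest other being 101. For lists, the real count, the highest other and the splits as large were 8, 8 and 2 in B-like cells, 11, 21 and 5 in cholangiocyte-like cells, 13, 13 and 2 in cDC1-like cells, 6, 16 and 7 in mesothelial-like cells and 17, 20 and 2 in neutrophil-like cells. They were 9, 14 and 4 in NK/ILC1-like cells, 0, 10 and 10 in plasma-like cells, 9, 17 and 8 in stellate/fibroblast-like cells and 13, 14 and 4 in T-like cells.

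The split of control 1, control 2 and knockout 2 from control 3, knockout 1 and knockout 3 called 1121 genes summed over 10 classes, against 2 for the real groups. It was picked as the split with the highest sum, and 759 of the genes came from stellate/fibroblast-like, 184 from plasma-like and 101 from T-like cells, with 0 in cholangiocyte-like, mesothelial-like and neutrophil-like cells. The first 3 libraries had the lowest median UMIs per barcode (5691, 4695 and 5553, against 7345, 5889 and 6110). The make-up of the stellate/fibroblast-like class also ran with the split. Cluster 17, led by smooth muscle genes, held 1.538%, 4.372% and 1.185% of kept cells in the first 3 libraries, where the class held 2.205%, 5.621% and 1.864%. In the others it held 0.6747%, 0.1708% and 1.049%, where the class held 4.343%, 0.8113% and 2.607%. Whether this mix accounts for the 759 genes was not tested. The labels name no batch, and each side holds both genotypes. With this split as a term Il23r in T-like cells was -0.95 (adjusted p = 0.0145), Ccl5 in cDC1-like cells -1.32 (adjusted p = 0.00941) and Sting1 in endothelial-like cells -0.56 (adjusted p = 0.671). Since the split was picked for the genes it called in these same sums, these adjusted p values are no independent check of the calls.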
